A study of Arabidopsis thaliana with 6 samples.

How the data were processed

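Poly(A) RNA from whole Arabidopsis thaliana seedlings, 7 days old, was sequenced in 6 libraries, 3 from the wild-type accession Col0 and 3 from the cbe1 mutant. Per the labels' protocols the seedlings grew on plates with 1% sucrose under 16 hours of light and 8 hours of darkness, and the whole seedlings were frozen and homogenised. The labels call the 3 libraries of a group biological replicates. The hour of harvest and the kind of mutation are not given in the sources used here.

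Per the submitters' processing notes, reads were aligned with TopHat and compared with Cuffdiff on genome build TAIR10, with no versions given. The authors' deposited table holds 1 FPKM value per gene and group (fragments scaled to transcript length and to the mapped fragments of the library), and no value per library. How the libraries were scaled to each other and whether strand was used are not given in the sources used here. The authors' deposited table also holds a test statistic, a p-value and a q-value per gene. On the table itself, the p-value differed by at most 2.74e-06 from the two-sided normal p of the statistic. The q-value differed by at most 2.46e-06 from a Benjamini-Hochberg adjustment over the genes marked as tested. Of 33557 genes, 22303 were marked as tested, 11198 were left untested by the authors for low signal, and 33, 14 and 9 carried the marks LOWDATA, FAIL and HIDATA. Genes at 0 with the mark HIDATA include some that every green tissue expresses, so those zeros were treated as failed estimates.

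Because the table gives only group values, no error bar per gene, no depth per library and no comparison between replicates could be computed, and depth is unknown. From 10 to 30 FPKM the ratio of the log2 fold change to the statistic had a median of 0.21 (5th to 95th percentile 0.18 to 0.35). From 1 to 3 FPKM it was 0.40 (0.26 to 1.31), and from 100 to 1000 FPKM 0.18 (0.17 to 3.30). Up to 1000 FPKM, at the median, a given fold change thus passed more easily in a more abundant transcript, with a wide spread between genes. Above 1000 FPKM the ratio was not computed.

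A gene was called when marked as tested with a q-value below 0.05. Log2 fold changes are those of cbe1 over Col0, from the deposited FPKM with no pseudocount. Before the data were examined, 26 gene lists were fixed, with 439 genes in all. For each list and direction, calls were compared with those among all other tested genes by a one-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 52 tests. Each list also has a count of calls adjusted over the list alone. All Fisher tests on lists, families and motifs are exact and, unless said otherwise, one-sided. The median fold change of a list is placed among 10000 random lists of the same size matched on mean FPKM in 20 bins. Gene families were formed from the letters that open a symbol, at least 3 letters and 8 tested members, which gave 199 families, tested in the same way. Genes are not independent of each other, so these tests describe these libraries.

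Coordinates are TAIR10, from the deposited table, counted from 1, and a locus can be shared by overlapping genes, as 4249 genes were. Symbols, biotypes, exon lengths and sequence upstream of genes come from the RefSeq annotation of the TAIR10.1 assembly, in which 32810 of the 33557 gene identifiers were found. Of the 133 plastid genes, 110 were given a name by an exact match of coordinates.

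CBE1 was matched to AT4G01290 from knowledge of the study, and the reference annotation gives the product of this gene as chorismate synthase. The genes named were set by a rule written before the data were examined. It takes CBE1, the 10 calls with the largest rise and the 10 with the largest fall that had FPKM above 0 in both groups and at least 1 in the higher one, and up to 3 calls per direction listed at 0 in 1 group. From each list it takes up to 4 calls by size of change, filled to 2 with the most abundant members. It adds up to 4 calls within 100 kb of CBE1 and up to 3 per enriched family. Any other gene name was chosen after its values were seen, also where this is not repeated beside the name.

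The alternatives tried were a q-value threshold of 0.01, a log2 fold change of at least 1, a mean FPKM of at least 1, pseudocounts of 1 and 0.1, rescaling to TPM, and recentring on the median gene. Further ones were added after seeing the data: a test statistic recentred on the median gene or on the nuclear protein-coding total, and a restriction to nuclear protein-coding genes that are alone on their locus and have at least 300 exon bases. The steps were tested on simulated data: of 200 genes changed among 21144, the test found 6.5% at a fold of 1.5, 45.0% at a fold of 2.0 and 85.5% at a fold of 4.0. The simulation drew normal noise from the deposited ratio of fold change to statistic, with as many rises as falls and no shift of all genes. It takes this error model as given, so the share found in the real data can differ. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.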

Results

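Whole seedlings of wild-type Col0 and of the cbe1 mutant were compared by poly(A) RNA sequencing, with 3 libraries per genotype. CBE1 (Conserved Binding of eIF4E 1) is a plant protein that binds the cap-binding translation factor eIF4E. The comparison asks which transcripts differ in seedlings of the mutant. All FPKM values are the authors' group values, which carry no spread between replicates, the depth of the libraries is unknown, and q-values are those of the authors' deposited table.

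The CBE1 transcript itself (AT4G01290, chromosome 4, 537990 to 543869, TAIR10) fell 3.07-fold, from 13.8 FPKM in Col0 to 4.48 FPKM in cbe1. Its log2 fold change was −1.62, with q = 1.41e-12 in the authors' deposited table. The gene was alone on its locus. Rescaling to TPM adds 1.57 to every log2 fold change alike, so there CBE1 came to −0.051 and was no longer past the threshold. That outcome tests nothing about CBE1. With the statistic recentred on the median gene its log2 fold change was −1.79 and the call was kept. Transcript from the gene was still present in the mutant, and the gene-level value does not show which part of it.

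Of 22303 tested genes, 1101 (4.94%) were called, 738 higher and 363 lower in cbe1. The called genes had a median log2 fold change of 0.84 when higher and −0.85 when lower, and the smallest called change was 0.53. The median of the 18727 tested genes with a mean FPKM of at least 1 was itself shifted by 0.17 on the log2 scale, a 1.13-fold rise. With the authors' statistic recentred on that median gene, an alternative chosen after seeing the data, 296 genes were called higher and 666 lower. All 363 lower calls and 296 of the 738 higher calls remained. Recentred on the nuclear protein-coding total the split was 511 higher and 457 lower. These recentred tests moved the balance of higher and lower calls. Recentring the fold changes of the deposited calls alone left 67.0% of them higher, as each call is larger than the shift. TPM adds 1.57 to every log2 fold change by construction, largely through the single short gene AT2G01021, which puts 93.2% of the calls above 0 and tests nothing.

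**Figure D1:**
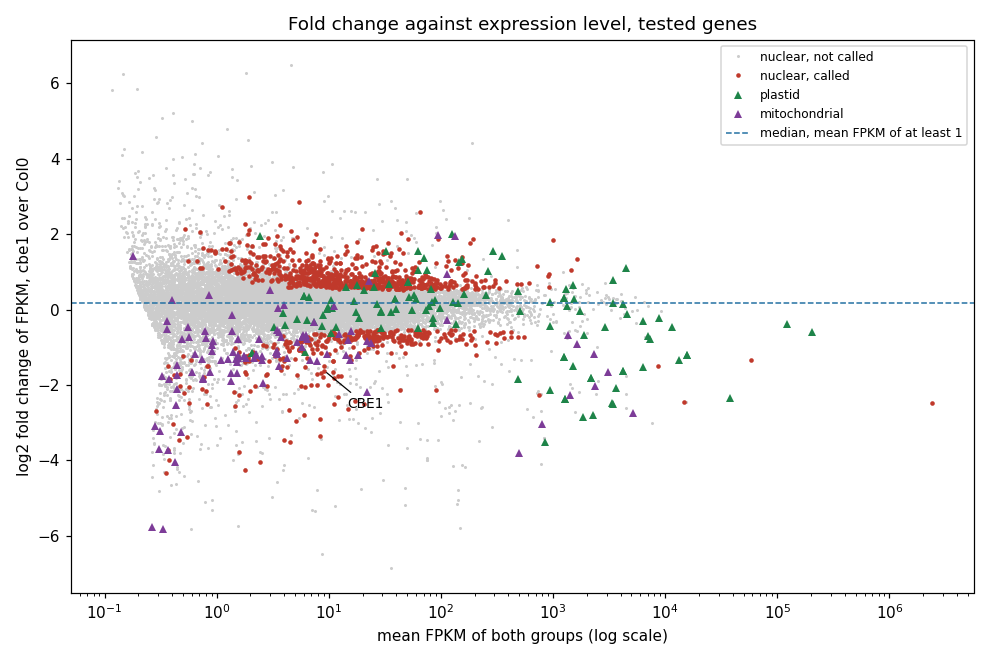
Log2 fold change of cbe1 over Col0 against the mean FPKM of both groups on a log axis, 1 point per tested gene with FPKM above 0 in both groups. Called nuclear genes are red, plastid genes green and mitochondrial genes purple, and the dashed line marks the median shift of 0.17. Mitochondrial genes lie mostly below the line, with a median of −1.20, and CBE1 lies at −1.62.

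Genes of mitosis were higher in cbe1. Of 30 tested genes of the mitotic list, which act in G2 and M phase, 13 rose and 0 fell, and 23 rose when adjusted over the list alone. CDC20.2, an activator of the anaphase-promoting complex, rose from 3.31 to 9.27 FPKM (log2 1.49). PLEIADE, a microtubule bundling protein of the cytokinetic phragmoplast, rose by 1.43 on the log2 scale, KNOLLE, the syntaxin of the forming cell plate, by 1.41, and the mitotic kinase CDKB1;1 by 1.40. In the authors' deposited table their q-values were 2.05e-05, 1.32e-04, 1.18e-08 and 0.0191. The list had more calls higher than other genes (Fisher's exact test, one-sided, odds ratio 22.7, adjusted p = 1.90e-10). With other settings the adjusted p of this exact test lay between 6.93e-15 and 8.54e-07. The median of 1.09, or 0.91 above the shift of all genes, lay at percentile 100 of the matched random lists, and on the log2(FPKM + 1) scale the median was 0.68. With the recentred statistic 8 members were called, and the call of CDKB1;1 was lost.

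Of 31 tested genes of G1 and S phase, 4 rose and 0 fell, and 7 rose when adjusted over the list alone. The replication helicase subunits MCM5 and MCM3 rose by 0.86 and 0.81 on the log2 scale, and the ribonucleotide reductase subunits RNR1 and TSO2 by 0.64 and 0.56. The excess of calls did not pass (Fisher's exact test, one-sided, adjusted p = 0.137), and none of the 4 calls was kept with the recentred statistic. The list median was 0.35, or 0.17 above the shift, at percentile 98.1. Of 10 CDK inhibitors and WEE1, 0 were called by the Cuffdiff test, 0 when adjusted over the list alone, and 0 had an unadjusted p below 0.05. SMR1 had 41.3 FPKM in Col0 and 41.5 FPKM in cbe1, and SIM had 14.7 and 17.1 FPKM. Of 9 DNA damage response genes only TSO2 was called, and it was also the only one when adjusted over the list alone. SMR5 had 3.14 and 6.90 FPKM and was not called.

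Of 15 tested circadian clock genes, 5 rose, 0 fell, and 8 rose when adjusted over the list alone. The hour of harvest of either genotype is not given in the sources used here. ELF4, a component of the evening complex, rose from 54.3 to 128.4 FPKM (log2 1.24). The pseudo-response regulators PRR3, TOC1 and PRR7 rose by 1.12, 0.94 and 0.69 on the log2 scale. PRR5 was the other call (log2 0.59; named after its value was seen). Calls were more frequent than among other genes (Fisher's exact test, one-sided, odds ratio 14.7, adjusted p = 0.00155). The list median was 0.53, or 0.35 above the shift, at percentile 99.98. With the recentred statistic ELF4, PRR3 and TOC1 were called, and the calls of PRR7 and PRR5 were lost. With a log2 fold change of at least 1 required, 2 calls were left and the excess no longer passed (exact test, adjusted p = 0.115; range over other settings 9.75e-04 to 0.0122). Of 26 flowering time genes 1 rose, also 1 when adjusted over the list alone: FKF1, a light-sensing F-box protein (log2 0.71), whose call was lost with the recentred statistic. The floral repressor MAF2 had 52.3 FPKM in Col0 and 39.5 FPKM in cbe1 and was not called.

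Of 18 tested genes of the cold, drought and ABA response, 6 rose, 0 fell, and 9 rose when adjusted over the list alone. KIN1 rose from 15.6 to 45.9 FPKM (log2 1.55). COR15B rose from 76.7 to 191.4 FPKM and COR15A from 91.9 to 215.0 FPKM; both encode chloroplast proteins that accumulate in the cold. CBF3, a transcription factor of the cold response, rose from 4.41 to 9.08 FPKM (log2 1.04), a call lost with the recentred statistic. Its relatives CBF2 (4.94 and 3.60 FPKM) and CBF1 (0.855 and 0.986 FPKM), named after their values were seen, were not called. Calls were more frequent than among other genes (Fisher's exact test, one-sided, odds ratio 14.7, adjusted p = 4.42e-04). The median was 0.44, or 0.26 above the shift, at percentile 99.9. KIN1 and KIN2, and COR15A and COR15B, are neighbouring gene pairs of similar sequence, so reads could have been split between the members.

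Seed storage and late embryo genes changed in both directions. Of 11 tested genes, 4 rose and 3 fell, and 4 rose and 4 fell when adjusted over the list alone. The 2S albumin genes SESA1, SESA3 and SESA2 fell, with log2 fold changes of −4.26, −3.78 and −1.71, from 3.43, 2.98 and 4.30 FPKM in Col0. The oil body protein gene OLEO2 rose from 6.71 to 21.7 FPKM (log2 1.69). The other rises, named after their values were seen, were the 12S globulin genes CRA1 (19.0 to 53.4 FPKM) and CRC (6.56 to 12.7 FPKM) and the oil body gene OLEO1 (3.66 to 8.99 FPKM). Both directions passed (Fisher's exact test, one-sided, adjusted p = 0.00424 higher and 0.00666 lower). The 3 lower calls are neighbouring 2S albumin genes on chromosome 4 (13607329 to 13612563). They need not be independent, so the lower result can rest on a single change. The list median was 0.38, or 0.21 above the shift, at percentile 93.6, and its mean −0.73, so the median and the mean differ in sign. The call of CRC was lost with the recentred statistic. Over nuclear protein-coding genes alone on their locus, the excess of higher calls missed the threshold (exact test, adjusted p = 0.0507; range over other settings 3.30e-04 to 0.00612).

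Translation initiation genes, the closest to the known partner of CBE1, had 1 call among 33 tested genes. EIF4G, the scaffold that eIF4E binds, rose from 8.08 to 12.2 FPKM (log2 0.59, q = 0.0400 in the authors' deposited table), and this call was lost with the recentred statistic. When adjusted over the list alone 3 members rose, and the excess of calls did not pass (Fisher's exact test, one-sided, adjusted p = 1). The median of 0.33, or 0.16 above the shift, lay at percentile 99.6. FBR12, an eIF5A gene, had 371.2 FPKM in Col0 and 475.9 FPKM in cbe1 and was not called. Of 20 genes of mRNA decapping, decay and surveillance, 0 were called by the Cuffdiff test and 0 when adjusted over the list alone, while 4 had an unadjusted p below 0.05. The most abundant members, DCP5 with 35.1 and 43.2 FPKM and LSM1A with 18.9 and 22.8 FPKM, were not among these. The list median of 0.17 equalled the shift of all genes after rounding.

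Of 24 antioxidant enzyme genes, CAT1 (log2 0.62) and TAPX (0.58) rose, and 10 rose when adjusted over the list alone. The excess of calls did not pass (Fisher's exact test, one-sided, adjusted p = 0.904), both calls were lost with the recentred statistic, and the median of 0.37, or 0.20 above the shift, lay at percentile 99.9. Of 13 flavonoid and anthocyanin genes, the early pathway genes FLS1 (log2 0.93), F3H (0.84) and TT4 (0.75) rose, and 4 rose when adjusted over the list alone. That excess did not pass over all tested genes (Fisher's exact test, one-sided, adjusted p = 0.0698) and passed among genes with a mean FPKM of at least 1 (exact test, adjusted p = 0.0243; range over other settings 0.0924 to 1). The call of F3H was lost with the recentred statistic. F3H and TT4 share their loci with another gene.

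Of 12 auxin response genes, IAA3 fell (log2 −0.58) and 0 rose, with 2 lower when adjusted over the list alone. The median of −0.26, or −0.43 relative to the shift, lay at percentile 0.11. IAA2 had 55.8 FPKM in Col0 and 41.9 FPKM in cbe1. With the recentred statistic 3 members were called lower and the list passed (Fisher's exact test, one-sided, adjusted p = 0.0413). As deposited it did not pass (exact test, adjusted p = 0.904), nor with any of the other settings (adjusted p from 0.868 to 1).

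Among the phosphate and nitrate genes, the phosphate starvation RNA IPS1 fell from 9.06 to 3.16 FPKM and the nitrate reductase gene NIA1 rose (log2 0.55), 2 calls in 13. When adjusted over the list alone 4 rose and 2 fell, and the list median (0.16, or −0.019 relative to the shift) and mean (−0.03) differ in sign. In the glucosinolate list CYP79F1 fell (log2 −0.73), the only call in 17 on either count, while CYP83A1 had 84.3 and 67.9 FPKM. LOX2, an enzyme of jasmonate synthesis, rose by 1.21 on the log2 scale, the only call among 11 jasmonate genes on either count, while PR4 had 130.5 and 131.8 FPKM. The iron transporter gene IRT1 rose (log2 0.85), the only call among 13 iron genes on either count, while FER1 had 70.7 and 55.1 FPKM. SEN1 rose (log2 0.95), the only call among 8 sugar starvation genes on either count, while DIN10 had 40.9 and 51.9 FPKM. For none of these 5 lists did the excess of calls pass in either direction. The calls of NIA1 and IRT1 were lost with the recentred statistic.

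Among markers of tissue make-up 2 lists held a call each. SPCH, which starts the stomatal lineage, rose from 0.591 to 1.99 FPKM, 1 call in 8, with 2 higher and 1 lower when adjusted over the list alone. STOMAGEN, the lower one, had 39.1 and 26.1 FPKM and was also called lower with the recentred statistic, but not over all genes as deposited. ANT, active in young organ primordia, rose by 0.78 on the log2 scale, 1 call in 5 shoot meristem markers on either count, and CLV1 had 12.9 and 10.1 FPKM. The calls of SPCH and ANT were lost with the recentred statistic, and neither list passed (Fisher's exact test, one-sided, adjusted p = 0.904 for each). Of 16 root markers 0 were called by the Cuffdiff test, with 2 at an unadjusted p below 0.05. The most abundant tested members were the root β-glucosidase PYK10, with 2440 and 1583 FPKM (p = 0.0597 in the authors' deposited table), and CASP1, with 19.4 and 29.8 FPKM (p = 0.00924 there). Of 20 nuclear photosynthesis genes 0 were called, with 3 at an unadjusted p below 0.05. The most abundant of the tested members, RBCS3B with 5964 and 6890 FPKM and LHCA1 with 5615 and 5563 FPKM, were not among these (p = 0.617 and 0.974 in the authors' deposited table). RBCS1A and LHCB1.2, more abundant in Col0 at 11658 and 12738 FPKM, were not tested by the authors and are listed at 0 in cbe1 as failed estimates. Most tested members lie above 1000 FPKM. There LHCB2.1, named after its value was seen, had 1654 and 2461 FPKM (log2 0.57) and was not called (q = 0.252 in the authors' deposited table). TAPX was called at 0.58, with 42.6 and 63.7 FPKM. The lack of calls in this list thus does not exclude changes of that size.

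The 4 other lists without a call were those of heat shock (16 tested), salicylate and pathogen defence (13), cytokinin (6) and RT-qPCR reference genes (10). In the 8 lists without a call, 0 genes were called when adjusted over the list alone, and 15 of 111 tested members had an unadjusted p below 0.05. ROF1 had 15.3 and 22.4 FPKM in Col0 and cbe1, and MBF1C 16.5 and 16.9 FPKM. NPR1 had 6.89 FPKM in both groups, EDS1 4.96 and 5.26 FPKM, ARR4 30.3 and 31.0 FPKM, and ARR6 8.78 and 7.09 FPKM. UBQ10 had 583.3 and 606.3 FPKM and EF1A 429.0 and 614.6 FPKM. The reference gene list had a median of 0.17, which equals the shift after rounding.

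**Figure D2:**
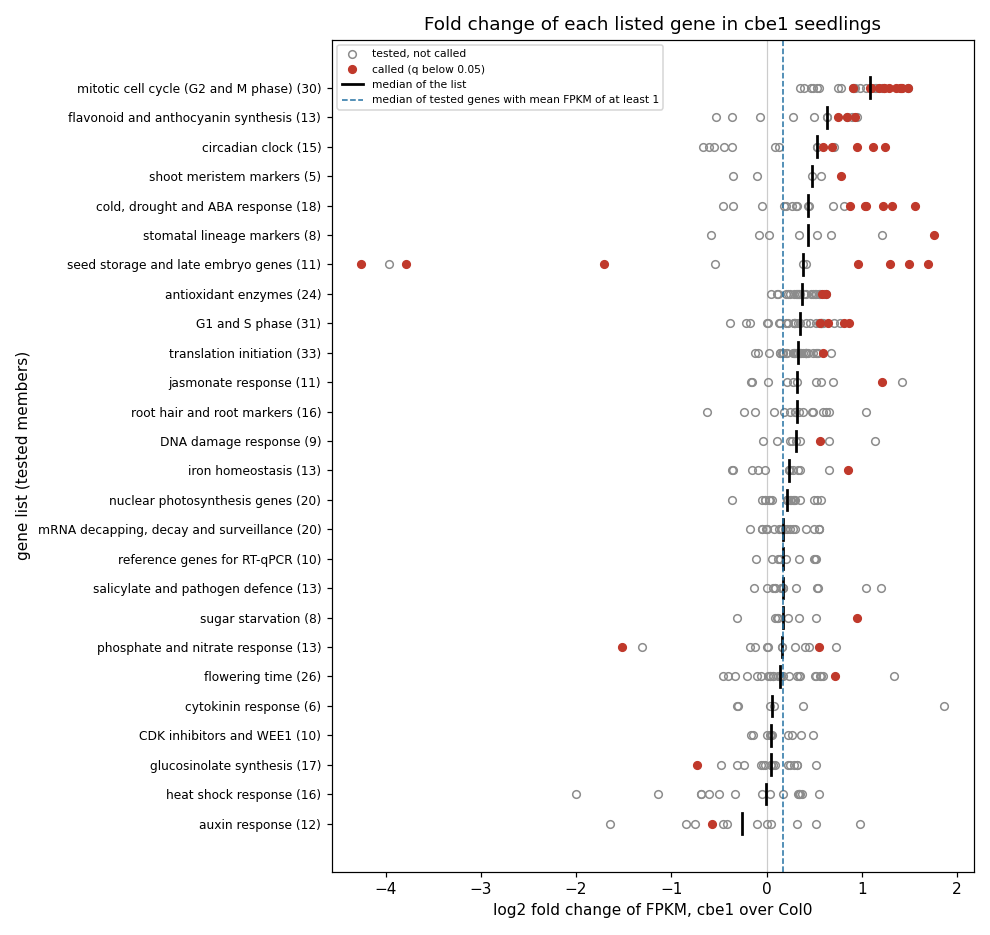
Log2 fold change of FPKM, cbe1 over Col0, for each tested member of the 26 gene lists with FPKM above 0 in both groups. Red points are called, open points are not, black bars are list medians, and the dashed line is the median shift of 0.17. The mitotic list has the highest median, 1.09, with 13 calls, and the auxin list the lowest, −0.26.

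Among 199 gene families, 8 family directions had more calls than other genes (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted). Lower calls were more frequent in 2 families of wall-modifying enzymes. In the XTH family of xyloglucan endotransglucosylases 5 of 26 fell (exact test, adjusted p = 0.00496), among them XTH7 from 399.9 to 218.0 FPKM, XTH32 (log2 −0.73) and XTH31 (−0.72). In the beta-galactosidase family 4 of 12 fell (exact test, adjusted p = 0.00496), among them BGAL1 (log2 −0.77), BGAL8 (−0.72) and BGAL5 (−0.71). Extensin genes, named for structural glycoproteins of the wall, rose in 4 of 8 cases (exact test, adjusted p = 0.00496). Among them were EXT13 at 1.15, EXT11 at 0.98 and EXT6 at 0.95 on the log2 scale, of which EXT11 is annotated as a pseudogene. At a q-value threshold of 0.01 the XTH family no longer passed (exact test, adjusted p = 0.684). Grouped by protein name instead of symbol, neither beta-galactosidases nor xyloglucan endotransglucosylases passed with the deposited statistic. Both passed with the recentred one.

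Of 8 COR genes 4 rose (exact test, adjusted p = 0.00496). COR27 rose from 9.58 to 24.7 FPKM, and COR15A and COR15B belong to the cold list too. Of 21 genes with HSP symbols 6 rose (exact test, adjusted p = 0.00496), among them Hsp70-2 (log2 1.41), the plastid chaperone HSP93-III (0.89) and Hsp89.1 (0.82). The heat shock response list, which holds some of the HSP genes but none of the called ones, had 0 calls, with 3 members at an unadjusted p below 0.05, and a median of −0.01. Some HSP genes are similar copies that can share reads. EMB genes, named for embryo-defective mutants, rose in 18 of 157 cases (exact test, adjusted p = 0.00190), among them the condensin gene EMB2795 (log2 1.28), EMB3120 (1.03) and EMB2768 (0.98). ABCG transporters rose in 6 of 31 cases (exact test, adjusted p = 0.0265), led by ABCG8 (log2 1.58), ABCG13 (1.12) and ABCG30 (1.04). PTAC genes, for proteins of the plastid chromosome, rose in 4 of 14 cases (exact test, adjusted p = 0.0454), led by PTAC3 (log2 1.04), PTAC2 (0.71) and PTAC17 (0.66). With the recentred statistic the EMB, ABCG and PTAC families no longer passed (exact test, adjusted p = 0.126, 1 and 1), and the calls of EMB2795, ABCG8, ABCG13, ABCG30, PTAC2 and PTAC17 were lost.

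The largest rises among single genes were led by CHX17 (AT4G23700, chromosome 4, 12342428 to 12346043), a cation/proton exchanger, from 0.435 to 3.42 FPKM (log2 2.97, q = 4.07e-10 in the authors' deposited table). The lipid transfer protein gene AT4G12490 rose by 2.86, the retroelement SADHU3-2 by 2.73 and SAMDC (AT3G02470), a gene of polyamine synthesis, by 2.58 on the log2 scale. SAMDC rose from 18.8 to 112.3 FPKM, and AT3G02468 on the same locus fell from 239.3 to 141.1 FPKM. These opposite changes are of similar size in FPKM, so the values show no clear rise of the locus as a whole. Whether reads were divided differently between these genes was not tested. The other rises of this group were AT1G58070 (2.28), AT1G03200 (2.25), AT4G14020 (2.14), AT4G15680 (0.738 to 3.17 FPKM), the chitinase gene AT2G43620 (2.08) and PSD2 (2.06). The calls of AT1G03200 and AT4G15680 were lost with the recentred statistic, at log2 fold changes of 2.07 and 1.93 relative to the shift.

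Besides SESA1 and SESA3, the largest falls were those of SESA5 (log2 −4.04), AT4G06477 (−3.51), the defensin-like gene LCR67 (−3.45), AT1G68250 (−3.34) and the mitochondrial gene ATMG00030 (−3.04). The small nuclear RNA genes U2.3, U2.7 and U2.4 fell too (−2.96, −2.91 and −2.80); each shares its locus with other genes, and the U2 copies are similar in sequence. AT4G19112 had 4.19 FPKM in Col0 and was listed at 0 in cbe1, on a shared locus.

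Transcripts of the organelles differed by compartment. Mitochondrial genes summed to 32158 FPKM in Col0 and 12665 FPKM in cbe1, and plastid genes to 665126 and 415301 FPKM. These sums are values with no test. Of 111 tested mitochondrial genes 18 fell and 0 rose. Of 129 tested plastid genes 12 rose and 6 fell. Among the falls, ATCG00860 and ATCG01280 both match ycf2, and ATCG00970 and ATCG01160 had the same FPKM in cbe1. The 6 falls are thus not 6 distinct genes. The ATP synthase gene atpH rose from 171.4 to 351.2 FPKM. On the log2 scale psaA and psaB of photosystem I rose by 1.05 and 1.06, and ndhJ by 1.54. The short gene trnS fell, with a log2 fold change of −2.33, and so did the longer genes rpoC2 (−1.14) and ycf2 (−1.16). All were named after their values were seen. Organelle genes took 12.3% of summed FPKM in Col0 and 22.4% in cbe1. Without AT2G01021, a short gene on chromosome 2 (6571 to 6672) that alone held 72.2% and 38.8% of the sums, the organelle shares were 44.3% and 36.6%. Organelle loci of at least 300 bases took only 3.13% and 2.03% of these sums, so most of the organelle FPKM came from shorter loci. Some plastid genes, such as ATCG00920, were listed at 0 with the mark HIDATA and add nothing to the sums. AT2G01021 weighs most on the TPM scale. It lies beside the nuclear ribosomal RNA genes, and the origin of its reads was not tested, so its FPKM need not stand for a short transcript.

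Around CBE1, 3 of 42 tested genes within 100 kb were called, and an excess or lack of calls there was not detected (Fisher's exact test, two-sided, odds ratio 1.48, p = 0.463). Besides CBE1 they were PPa5 (AT4G01480, log2 0.86), a soluble pyrophosphatase gene, and WTF1 (AT4G01037, 0.73), whose call was lost with the recentred statistic. With CBE1 itself left out, 2 of 41 genes were called (odds ratio 0.99). Of 240 windows of 500 kb, 2 held more calls than the rest of the nuclear genome (Fisher's exact test, one-sided). On chromosome 2, from 3000001 to 3500000, 21 of 93 tested genes were called, 20 of them lower (exact test, adjusted p = 6.03e-07). On chromosome 3, from 21000001 to 21500000, 17 of 126 were called, 10 higher and 7 lower (exact test, adjusted p = 0.0143), and 4 of the 7 were U2 small nuclear RNA genes.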

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

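These values were singled out only after they were seen, and no test was run. In 3 genes that the authors' test left out, the level in cbe1 was above that in Col0 by a wide margin. AT5G09670, marked FAIL, was at 14.2 FPKM in cbe1 and 0.459 FPKM in Col0. Its partner on the same locus, AT5G09672, also marked FAIL, went the other way, from 12.9 to 0.125 FPKM. These opposite changes are of similar size in FPKM, so the values do not show a clear rise of the locus as a whole. XPL1 (AT3G18000), marked FAIL, was at 9.24 FPKM in cbe1 and 2.54 FPKM in Col0, and shares its locus with AT3G17998, at 22.7 and 24.1 FPKM. AT4G25692, marked LOWDATA and on a shared locus, was at 1.43 FPKM in cbe1 and 0.425 FPKM in Col0. The authors' table gives no test for them.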

How the results depend on the processing

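Of the tests here, those named as chosen after seeing the data were chosen only after the results were seen. No paired analysis was possible because the values are given per group and not per library. For the same reason the replicate block was not run, no replicate could be left out in turn and no other split of the samples could be refitted, so how far 1 library decides a value is not known, and depth is unknown. The recentred statistic, the nuclear protein-coding total and the restriction to nuclear protein-coding genes were chosen after seeing the data. At a q-value threshold of 0.01, 562 genes were called, 355 higher and 207 lower, and with a log2 fold change of at least 1, 386, with 240 and 146, since both settings are stricter. Recentring the statistic on the median gene gave 296 higher and 666 lower, and recentring on the nuclear protein-coding total 511 and 457. Of the calls, 67.0% were higher as deposited, 93.2% after TPM, which moves each gene by the same amount, and 69.9% among nuclear protein-coding genes alone on their locus. TPM also took CBE1 to −0.051, no longer past the threshold, by the same shift of every gene, largely through AT2G01021. That tests nothing about CBE1. By list, the clock had 2 calls with a log2 fold change of at least 1 and no longer passed, and late embryo genes 3 higher calls among nuclear protein-coding genes. The auxin list passed with 3 lower calls under the recentred statistic and the flavonoid list with 3 at a mean FPKM of at least 1. The causes of these list changes were not tested. At a q-value of 0.01, 4 family directions passed instead of 8, with XTH, EMB, ABCG and PTAC lost, and at a mean FPKM of at least 1 there were 6, with ABCG and PTAC lost. The log2 ratio of organelle sums went from −0.70 to −1.05 on loci of at least 300 bases. No entry of the table named several genes, so leaving such entries out moved nothing. Of 235 recalculations for 79 named calls, 184 stayed past the threshold and 51 did not, 26 at a q-value of 0.01 and 25 with the recentred statistic; these settings could not turn a direction, and TPM was not among them. The calls lost at a q-value of 0.01 were those of ABCG8, ABCG13, ABCG30, ANT, AT1G03200, AT4G15680, CAT1, CBF3, CDKB1;1, EIF4G, EMB2795, F3H, IAA3, IRT1, MCM3, MCM5, NIA1, PSD2, PTAC2, RNR1, SADHU3-2, SPCH, TAPX, TSO2, WTF1 and XTH32. AT4G19112, listed at 0 in cbe1, has no fold change to recalculate, and its q-value of 0.0201 in the authors' deposited table misses that threshold too. Of 78 recalculated list medians 72 stayed within their spread and 6 moved. Of the 6, 5 moved with recentring and that of the mitotic list, from 1.09 to 0.68, with log2(FPKM + 1). The spread is a bootstrap over the member genes of a list, not between libraries, and can be wide for short lists. At a mean FPKM of at least 1 the shoot meristem median went from 0.48 to −0.097 and still counted as within it. The heat shock median did so too, from −0.006 to 0.17. The count of 72 thus does not measure how stable the medians are across settings.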

Other observations

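The tests in this part were chosen only after the result was seen, apart from the match on GC content and exon length and the 3 upstream motifs. Genes were also grouped by the protein name of the reference annotation. Of 381 groups, 6 had more calls than other genes in 1 direction (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted). GDSL lipases fell in 12 of 48 cases (exact test, adjusted p = 9.04e-09), such as AT1G74460 from 25.6 to 11.5 FPKM and AT4G18970 from 124.5 to 69.8 FPKM. Secreted peroxidases fell in 9 of 52 cases (exact test, adjusted p = 2.75e-05), such as Prx37 from 19.8 to 5.82 FPKM. SAUR genes, induced by auxin in elongating tissue, fell in 8 of 67 cases (exact test, adjusted p = 0.00196), such as SAUR27 (9.93 to 4.51 FPKM) and SAUR23 (22.1 to 11.1 FPKM). Lipid transfer proteins rose in 14 of 65 cases (exact test, adjusted p = 7.35e-06), by 0.86 to 2.86 on the log2 scale, and proline-rich extensin-like proteins in 7 of 12 (exact test, adjusted p = 7.35e-06), such as AT1G23720 from 12.4 to 40.3 FPKM. Kinesins rose in 4 of 9 cases (exact test, adjusted p = 0.0167), such as ATK1 from 1.03 to 2.56 FPKM. With the recentred statistic 18 groups passed, these 6 and 12 others, of which 11 were lower, such as pectin lyase-like proteins, and 1 was higher, the TRAF-like proteins. The 11 include beta-galactosidases (5 of 12) and xyloglucan endotransglucosylases (6 of 24), with adjusted p of 0.00169 and 0.00449 in this exact test. Both had passed by symbol with the deposited statistic, but not by protein name. Extensin-like genes and lipid transfer genes often lie in clusters of similar copies, so reads could not always be assigned to 1 copy.

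With the recentred statistic 7 further families passed as lower. Arabinogalactan proteins of the FLA family were called in 6 of 14 cases (exact test, adjusted p = 2.71e-04), expansins in 5 of 18 (exact test, adjusted p = 0.00641) and TBL genes of wall acetylation in 7 of 37 (exact test, adjusted p = 0.00550). The others were SAUR with 5 of 16, PAP with 5 of 24, PME with 3 of 8 and SKS with 3 of 8 (exact test, adjusted p = 0.00515, 0.0247, 0.0440 and 0.0440). None of these 7 families, formed by symbol, passed with the deposited statistic. The SAUR genes grouped by protein name did pass with it (8 of 67, exact test, adjusted p = 0.00196).

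For the rise of the mitotic list, the tables argue against a GC content or exon length trend: the median lay at percentile 100 of 10000 lists matched on exon length, GC content and mean FPKM, of which the upper 2.5% began at 0.38. A shift of all genes is argued against by the recentred statistic, with which the list still passed (exact test, adjusted p = 2.07e-07). A larger share of dividing tissue in the mutant seedlings stays open, since the G1 and S phase list lay at percentile 98.1 and the shoot meristem list at 93.8, and cannot be told apart from a change within dividing cells without values by cell type. The meristem value rests on 5 genes, and its median went from 0.48 to −0.097 among members with a mean FPKM of at least 1.

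In a split of the clock list made after its values were seen, the 7 evening genes (TOC1, PRR3, PRR5, GI, ELF3, ELF4 and LUX) had a median log2 fold change of 0.59, at percentile 99.9 of matched lists, and the 5 morning genes (CCA1, LHY, PRR9, RVE1 and RVE8) one of −0.56, at percentile 0.34, although no morning gene and only 4 evening genes (TOC1, PRR3, PRR5 and ELF4) were called. PRR7, a call at 0.69, GRP7 at 0.71 and ZTL at 0.09 were in neither set, an assignment made after the values were seen. The difference of 1.15 (1.09 with PRR7 among the morning genes) is what a harvest at a different hour would give and equally what changed clock timing in cbe1 would give. Both stay open, as the labels give no hour of harvest.

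Mitochondrial genes had a median log2 fold change of −1.20 and small nuclear and nucleolar RNAs of −1.90, both below all 10000 lists matched on mean FPKM. Both are what less carry-over of RNA without poly(A) tails into the cbe1 libraries may give, as would the fall of AT2G01021, which lies beside the nuclear ribosomal RNA genes. For the plastid part it cannot be told apart from other causes, since 7 genes alone on their locus rose while the plastid sum was lower, with a log2 ratio of −0.68. Whether short length accounts for the small RNAs cannot be told apart either: only 27 of the 61 had at least 5 protein-coding genes in their length class, and the lowest 2.5% of the matched lists lay below −2.03. Short protein-coding genes were lower too. Their median was −0.46 under 200 exon bases and −0.37 from 200 to 400. It was 0.15 from 400 to 1000 bases and 0.25 above 4000. The window on chromosome 2 with 20 lower calls lies where the nuclear genome carries a copy of mitochondrial DNA, and the origin of its reads was not tested.

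As hypotheses of shared regulation, 3 upstream motifs were searched on either strand of the 500 bases upstream of genes called higher, the related list left out, and compared with other tested genes (Fisher's exact test, one-sided, adjusted over 3 motifs). The evening element AAAATATCT was present in 8.04% against 4.43% (odds ratio 1.88, exact test, adjusted p = 7.28e-05), and a scramble of it, ATCAATATA, was not enriched (odds ratio 0.86). It was also enriched among genes called higher with the recentred statistic (odds ratio 1.85, exact test, adjusted p = 0.0223). The MSA element YCYAACGGYY of mitotic promoters was present in 2.71% against 1.63% (odds ratio 1.68, exact test, adjusted p = 0.0399). With the recentred statistic the MSA element did not pass (odds ratio 1.59 over 269 genes called higher in place of 701, exact test, adjusted p = 0.246). Its reversed sequence was found in 1 of 701 genes called higher and 68 of 19996 others (odds ratio 0.42). That is too rare for this control to show whether the enrichment is specific. The ABA response element ACGTGGC did not pass (odds ratio 1.27, exact test, adjusted p = 0.0769), and with the recentred statistic its odds ratio was 1.06 (exact test, adjusted p = 0.456), so no enrichment was detected.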
